A study of Homo sapiens with 4 samples.

How the data were processed

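Peak lists of 3 H3K27ac ChIP-seq libraries from K562 cells were used, 1 each for control shRNA, TFAM hairpin 1 and TFAM hairpin 2. The groups were taken from the sample titles. Per the labels' protocols, cells were grown in IMDM with serum, libraries were made with a NEBNext ChIP-seq kit and sequenced on an Illumina NextSeq500, and reads that fitted only 1 place in hg19 were kept. The antibody was an Abcam product, per the labels. Bowtie 0.12.7, Picard and hg19 are named, per the submitters' processing notes, without their roles. From the peak names, the peaks carry a MACS prefix. The version of the caller, its threshold, its use of the input and the read depth were not given in the sources used here. The input library was not analysed here.

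Each deposited list gives the start, end and a score per peak as the authors made them, with no pooling of libraries. The score is the authors' own value for the peak; it was 50 or more in the control list and reached 3100. Scores were used only to rank peaks within a list, because lists of different depth are not on a common scale. All peaks lay inside the lengths of the 25 reference chromosomes of GRCh37. The peak widths ran from 208 to 8704 bp in the control, 239 to 8781 bp in hairpin 1 and 221 to 8841 bp in hairpin 2. Positions are given 1-based in hg19.

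Peaks of the 3 lists that overlapped by at least 1 bp were joined into union regions, and each region was classed by the lists with a peak in it. The count of gained or lost regions expected if no library stood apart was taken from a conditional model with 1 term per library, fitted to the classes with a peak in some lists but not in all, with 95% of 10000 draws as its range. The count under independent lists was the product of the regions gained, or lost, in each hairpin divided by a number of regions. For gained regions that number was all 33834 union regions, and for lost regions the 23150 with a control peak. Overlap between lists was given as the share of peaks and as the Jaccard index of base pairs. Widths were compared as log2 ratios of covered base pairs per region. G+C content was computed from the GRCh37 sequence on a grid of 10 bp, and regions were divided into 5 groups of like size by it.

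Genes came from GENCODE release 44 mapped to GRCh37, with 20149 protein-coding genes. The start site was that of the canonical transcript in 19869 genes and the gene's 5' end in the others. A promoter was the start site with 1 kb on each side, and regions were classed as promoter, exon, intron or intergenic in that order. A table of gene names on another assembly was not used here. For each gene the base pairs covered by peaks within 5 kb of the start site were summed. For 20 lists holding 310 distinct genes, all of them annotated, the mean difference of the hairpins from the control was placed among 10000 random lists of the same size, matched on deciles of covered base pairs. These percentiles describe the 3 libraries and are no test of the condition, and a list was said to lie outside below 2.5 or above 97.5. Symbol families with at least 20 covered genes were treated in the same way.

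Genes were named by a rule: the 12 gained regions with the highest smaller score percentile in the hairpin lists, the 12 lost regions with the highest control score percentile, up to 4 members of each gene list with a gained or lost promoter or otherwise the 2 with the most covered base pairs, and TFAM with the globin clusters. Some genes that the rule names are not reported here. Names outside that rule are said to have been chosen after their values were seen. The lists, the naming rule, the comparisons and the first set of alternatives were fixed before the data were examined.

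The code was tested on simulated data made on the 33834 union regions. The class counts came out exactly in 40 of 40 simulations. With no added regions the gained count exceeded its range in 0 of 40, with 500 regions added to both hairpins in 29 of 40 and with 1000 in 40 of 40. On the 20149 genes, 7 of 100 random lists of 15 genes lay outside the central 95%, 49 of 100 did so with 500 bp added per gene and 94 of 100 with 1000 bp.

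Alternatives tried were the higher-scoring 50% of each list, equal list lengths, a minimum overlap of 50% of the shorter peak, peaks within 1 kb merged, autosomes alone, each hairpin alone, promoters of 2.5 kb on each side, gene bodies with 10 kb on each side, and absence defined as no peak within 1 kb. Chosen after seeing the data were regions and genes with peaks under 5 kb, the start sites of all basic transcripts, and random lists matched also on promoter G+C, on the widest nearby peak, or on sequence covered within 25 kb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.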

Results

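H3K27ac, a histone acetylation mark of active promoters and enhancers, was mapped by ChIP-seq in K562, a human erythroleukaemia line used as a model of early red cells. The cells carried either a non-targeting control shRNA or 1 of 2 shRNAs (hairpin 1 and hairpin 2) against TFAM, the protein that packages mitochondrial DNA and starts its transcription. The stated interest of the series was how excess histone acetylation in TFAM-deficient erythroid cells changes H3K27ac across the genome. Each condition was represented by 1 library with 1 peak list, so no p-value and no spread between replicates is given anywhere. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. An input library of K562 was not analysed here. Read depths were not given in the sources used here. The control list held 23413 peaks over 52.1 Mb of hg19, the hairpin 1 list 23819 peaks over 54.4 Mb and the hairpin 2 list 27007 peaks over 61.9 Mb. Median peak widths were 1952, 1996 and 1960 bp, in the same order.

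The promoter of TFAM itself was marked in every library. Its peak lay on chromosome 10 at 60143759 to 60146741 in the control and spanned 2983 bp there, 2787 bp in hairpin 1 and 2447 bp in hairpin 2. It ranked at score percentile 91.6 of the control list, 89.6 of the hairpin 1 list and 92.9 of the hairpin 2 list. H3K27ac at this promoter does not measure the knockdown, because an shRNA acts on the transcript. The globin clusters, which encode the chains of haemoglobin, were marked in all libraries as well. The alpha-globin cluster with 50 kb on each side (chromosome 16, 152643 to 280458) held 9 control peaks over 30943 bp. It held 10 hairpin 1 peaks over 28040 bp and 6 hairpin 2 peaks over 22168 bp. The beta-globin cluster with 50 kb on each side (chromosome 11, 5198301 to 5341175) held 3, 4 and 3 peaks over 5241, 6892 and 5134 bp. Both intervals extend past the globin genes, so a difference in their totals need not lie at those genes. HBZ, the embryonic alpha-like globin, kept a promoter peak in every list, with 4555 bp covered in the control, 3497 bp in hairpin 1 and 5764 bp in hairpin 2. HBA1, an adult alpha-globin, had 1674, 3564 and 2123 bp covered near its start site but no peak at its promoter in any list. HBA1 and HBA2 are near-identical copies, as are HBG1 and HBG2, and reads that fit more than 1 place were not kept, so the absence of a peak there says little.

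The first comparison asked how much H3K27ac-marked chromatin was listed with and without TFAM shRNA. Hairpin 1 had 1.73% more peaks than the control and 4.34% more covered sequence, while hairpin 2 had 15.4% more peaks and 18.7% more covered sequence. Of the control peaks, 79.0% (78.5 to 79.5) overlapped a hairpin 1 peak and 83.4% (82.9 to 83.9) a hairpin 2 peak. Of the hairpin 1 peaks, 79.9% (79.4 to 80.5) overlapped a hairpin 2 peak. By shared base pairs the hairpin libraries were no closer to each other than to the control: the Jaccard index was 54.8% between the hairpins, 57.8% between control and hairpin 1 and 57.1% between control and hairpin 2. Among the 16871 regions with a peak in all 3 lists, the median width was 2262 bp in the control, 2348 bp in hairpin 1 and 2527 bp in hairpin 2. The median log2 width ratio was 0.05 for hairpin 1 over control (quartiles -0.21 and 0.32), 0.12 for hairpin 2 over control (quartiles -0.11 and 0.41) and 0.08 for hairpin 2 over hairpin 1. The control was the narrowest of the 3 libraries in 42.6% of these regions (41.9 to 43.4), hairpin 1 in 35.3% and hairpin 2 in 21.9%. The hairpins differed from each other by about as much as from the control, and neither the peak number nor the width of a list can be separated from depth and peak calling here.

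The second comparison asked which regions both hairpins gained or lost relative to the control. A region was called gained when both hairpin lists had a peak and the control had none, and lost when the control alone had one. No list held a peak wider than 8841 bp, and whether wider domains were left out of the lists is not known. The absence of a peak therefore does not show that a region was unmarked. The gained region that ranked highest by score was the promoter of MLLT10 (chromosome 10, 21821250 to 21825428), a leukaemia fusion partner that recruits the H3K79 methyltransferase, covered for 3851 bp in hairpin 1 and 4050 bp in hairpin 2. The neighbouring promoter of SKIDA1 (chromosome 10, 21812298 to 21818832) was gained as well. NR4A2, an orphan nuclear receptor induced by stress signals, was gained at chromosome 2, 157187579 to 157193831. TSPO, a cholesterol- and porphyrin-binding protein of the outer mitochondrial membrane, was gained at chromosome 22, 43546949 to 43549340, over 2364 bp in hairpin 1 and 2280 bp in hairpin 2. Gained promoters of similar rank were those of SETD5, NIPBL (the cohesin loader) and PHF21A (a reader in the LSD1 complex).

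The remaining top-ranked gained regions were the promoters of CCDC71L, CACYBP and RBM41 and intergenic regions 3739 bp from the start site of RPS6KC1 and 124687 bp from that of PABPC4L. Of the 12 gained regions named by rank, 10 were promoters. The lost region that ranked highest was the promoter of SLC25A1 (chromosome 22, 19164223 to 19167601), the mitochondrial citrate carrier whose export feeds acetyl-CoA synthesis in the cytosol. Its control peak spanned 3379 bp at score percentile 99.9 of the control list. An intergenic region 5086 bp from the same start site (chromosome 22, 19157906 to 19161163) was lost too, from score percentile 99.7. Other lost promoters among the 12 were those of SKI, a repressor of TGF-beta signalling (chromosome 1, 2157880 to 2161533), and PI4KA, a phosphatidylinositol kinase (chromosome 22, 21210290 to 21215644). Lost exonic regions included those nearest to the start sites of TRIM11 and VILL. Lost intronic regions were nearest to TBC1D5 and ARHGAP22, and lost intergenic regions to LAPTM5 and RIMBP3C. Of the 12 lost regions, 4 lay on chromosome 22 between 19 and 22 Mb.

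Across the genome 33834 regions had a peak in at least 1 list, 16871 of them in all 3. Gained regions numbered 2001 and lost regions 2386. Regions absent only from hairpin 1 numbered 2441 and those absent only from hairpin 2 numbered 1452, while 3286 regions were in hairpin 1 alone and 5397 in hairpin 2 alone. If no library stood apart from the other 2, 2406 gained regions (95% of draws: 2332 to 2480) and 2791 lost regions (2704 to 2882) would be counted. Both counts lay below their ranges by the same number, as the model ties them, so this is a single result. Lists changing independently of each other would give 1156 gained and 800 lost regions by the counts used here. The observed counts were 1.73 times as high for gained and 2.98 times for lost regions. These values were 2.18 and 3.10 times with hairpin 1 as the reference and 2.70 and 2.49 times with hairpin 2. For gained regions the divisor included regions with a control peak, which could not be gained. The count of 1156 is therefore too low, and the gained values decide nothing and cannot be set beside the lost ones. Part of the excess for lost regions can come from the control library, with which both hairpins were compared. The gained count was also below its range with equal list lengths (1510 against 1843, range 1773 to 1912) and inside it in the higher-scoring 50% of each list (1049 against 1072, range 1023 to 1119). In that setting gained regions outnumbered the 855 lost ones, the reverse of the order with all peaks.

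**Figure D1:**
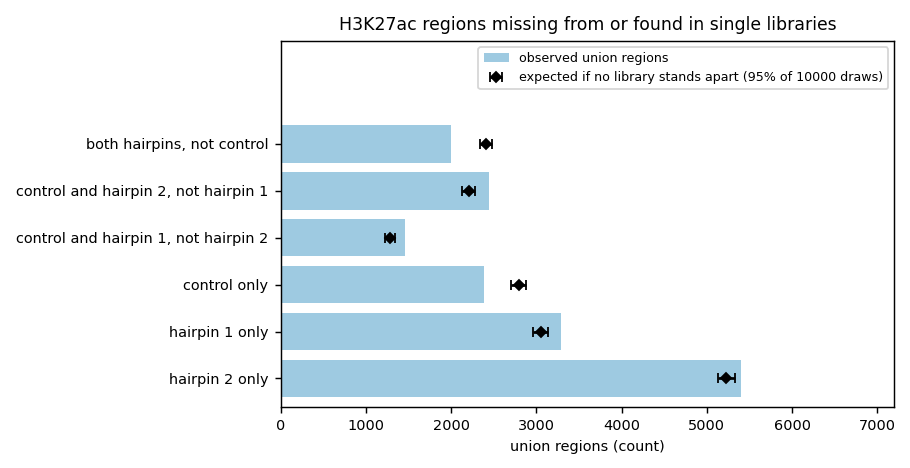
Number of H3K27ac union regions (x axis, count) by the libraries in which they had a peak (y axis), as bars, with black diamonds for the count expected if no library stood apart and error bars for 95% of 10000 draws. Regions in both hairpins and not the control (2001) and in the control alone (2386) lie below their expected counts of 2406 and 2791.

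Promoters made up most of the shared landscape and a smaller share of what differed. Of the regions in all 3 lists, 52.4% (51.7 to 53.2) overlapped a promoter, 11.7% an exon, 13.5% an intron and 22.3% lay between genes. Of the gained regions, 13.1% (11.6 to 14.7) were promoters, 18.6% exonic, 33.5% intronic and 34.8% intergenic. Of the lost regions, 6.50% (5.54 to 7.56) were promoters, 11.2% exonic, 39.98% intronic and 42.3% intergenic. In the higher-scoring 50% of each list the promoter share was 76.5% in all lists, 48.5% in gained and 15.4% in lost regions. Lost regions were poor in G+C, with a median of 40.9%, against 50.4% in gained regions and 50.5% in regions found in all lists. With the regions divided into 5 groups by G+C, 256 were gained and 1351 lost in the lowest group, and 509 were gained and 182 lost in the highest. The shared regions followed the same order, since their median log2 width ratio went from -0.33 to 0.21 in hairpin 1 and from -0.14 to 0.23 in hairpin 2 between those groups. Lost regions had a median score percentile of 15.6 in the control list and gained regions one of 25.05, compared with 65.1 for regions in all lists. Gained regions have peaks in 2 lists and lost regions in 1. Regions in hairpin 1 or hairpin 2 alone had median score percentiles of 16.0 and 18.0 and promoter shares of 8.76% and 5.76%. Regions absent only from hairpin 1 or only from hairpin 2 had 28.8 and 25.7, with promoter shares of 9.75% and 15.01%. With all peaks, the gained and lost values of score and promoter share therefore cannot be separated from the number of lists.

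**Figure D2:**
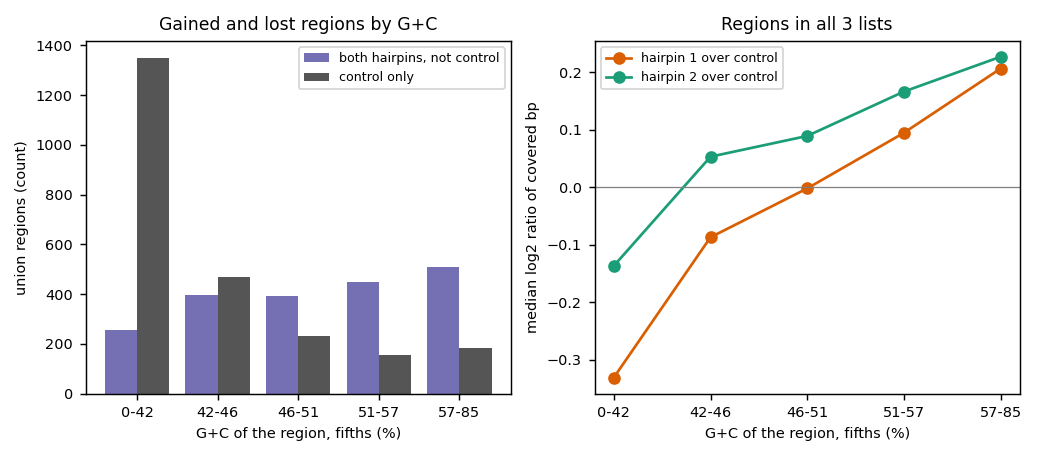
Left, number of gained regions (both hairpins, not control) and lost regions (control only) in each of 5 groups by G+C content; right, median log2 ratio of covered base pairs in the regions of all 3 lists, by the same groups, for each hairpin over the control. Lost regions number 1351 in the lowest group and 182 in the highest, and both ratios are higher in the highest group.

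The third comparison asked which genes had promoters that gained or lost H3K27ac, and whether gene groups fixed in advance moved together. Among the 20149 protein-coding genes, 10143 had a promoter peak in every list, 308 gained one in both hairpins and 167 lost one in both. In the higher-scoring 50% of each list 567 gained one and 148 lost one. Of 310 genes in 20 fixed lists, 4 changed in both hairpins. SLC4A1, the band 3 anion exchanger of the red cell membrane, was the gained one, with 0 bp covered in the control, 1917 bp in hairpin 1 and 3485 bp in hairpin 2. Its peak was at score percentile 16.9 in hairpin 1 and 64.4 in hairpin 2. Of the hairpin 1 peaks at score percentile 10 to 20, 53.8% had no control counterpart. GFI1B, a repressor needed for red cell and platelet development, was lost, from 5097 covered bp in the control to 0 in both hairpins. ATP5F1D, the delta subunit of ATP synthase, was lost from 4054 bp and HDAC9, a class IIa histone deacetylase, from 2505 bp. The counts of 308 and 167 lay, again by the same number, below the 351 (323 to 378) and 210 (185 to 235) of libraries that do not stand apart.

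Most nuclear genes for mitochondrial functions had a promoter peak in every list. Such promoters are called retained here, and genes that were not retained include those with no promoter peak in any list. Of 37 subunits of oxidative phosphorylation, 35 had a promoter peak in all lists, ATP5F1D was lost, and the mean covered length was 2946 bp in the control, 2820 bp in hairpin 1 and 2994 bp in hairpin 2 (percentile 8.12 among matched random lists). The percentile was 0.71 over gene bodies, 0.39 in the higher-scoring 50% of each peak list and 0.81 for genes with nearby peaks under 5 kb, a setting chosen after seeing the data. Of 15 genes of mitochondrial DNA maintenance and expression, 13 were retained and 2 had no promoter peak in any list, with means of 2228, 2413 and 2232 bp (percentile 36.4). Among those retained, LIG3, the mitochondrial DNA ligase, had 3835, 3509 and 3106 bp. LRPPRC, which stabilises mitochondrial mRNAs, had 3500, 2935 and 3061 bp. All 17 genes of the tricarboxylic acid cycle and acetyl-CoA supply were retained, with means of 2492, 2677 and 2707 bp (percentile 51.8), including CS, citrate synthase (4356, 4327 and 4249 bp), and MDH2, malate dehydrogenase (3639, 3397 and 3859 bp). Ketone body and acyl-CoA genes retained 11 of 15 promoters, with means of 2306, 2378 and 2776 bp (percentile 67.4). HADHA, of fatty acid oxidation, had 5855, 5681 and 5331 bp, and SLC16A1, a transporter of lactate and ketone bodies, had 4711, 4393 and 7109 bp. Of 27 acetyltransferase and deacetylase genes, 25 were retained, with means of 2864, 2907 and 3137 bp (percentile 40.2). Glycolysis genes retained 13 of 15 promoters, with means of 3234, 3236 and 3981 bp (percentile 71.5). Their ENO1, enolase, had 4678, 6819 and 7210 bp and GAPDH had 4998, 5245 and 5449 bp.

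Erythroid genes differed by group. Heme synthesis genes retained 7 of 11 promoters, with means of 3048, 3261 and 3209 bp (percentile 45.2, or 1.35 in the higher-scoring 50%); UROD, an enzyme of the pathway, had 4387, 4961 and 6401 bp and SLC25A38, the mitochondrial glycine carrier, had 5677, 2747 and 5881 bp. Of 11 iron handling genes 8 were retained and 2 had no promoter peak in any list, with means of 3296, 3692 and 3271 bp (percentile 49.3). Retained ones included the ferritin light chain gene FTL (7901, 8326 and 8354 bp) and the transferrin receptor gene TFRC (6095, 5799 and 6253 bp). Red cell membrane and surface genes retained 10 of 15, with means of 3430, 3487 and 3336 bp (percentile 19.5). Their percentile turned with the setting, at 1.02 with equal list lengths, 0.69 in the higher-scoring 50% and 99.8 with nearby peaks under 5 kb. Of the 10 globin genes 3 were retained and 6 had no promoter peak in any list, with means of 1321, 1484 and 1534 bp (percentile 62.1). The 14 erythroid transcription factors had means of 3266, 3085 and 1748 bp, and their mean difference from the control stood at percentile 0.04. That position came mainly from hairpin 2, which was below all 10000 random lists, while hairpin 1 was at percentile 16.9. In hairpin 2, but not in hairpin 1, the promoter peaks of TAL1 (5929, 5523 and 0 bp), ZFPM1 (5997, 6578 and 0 bp) and IKZF1 (6179, 6534 and 0 bp) were missing. These 3 genes, a core erythroid activator, the GATA1 cofactor FOG1 and the Ikaros factor, were chosen after their values were seen. LMO2, LDB1, MYB and ZBTB7A, chosen in the same way, kept a promoter peak in every list. GATA1, KLF1 and NFE2, also chosen in that way, had no promoter peak in any list. Without the read depth and the settings of the caller, such an absence does not show that a promoter was unmarked.

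**Figure D3:**
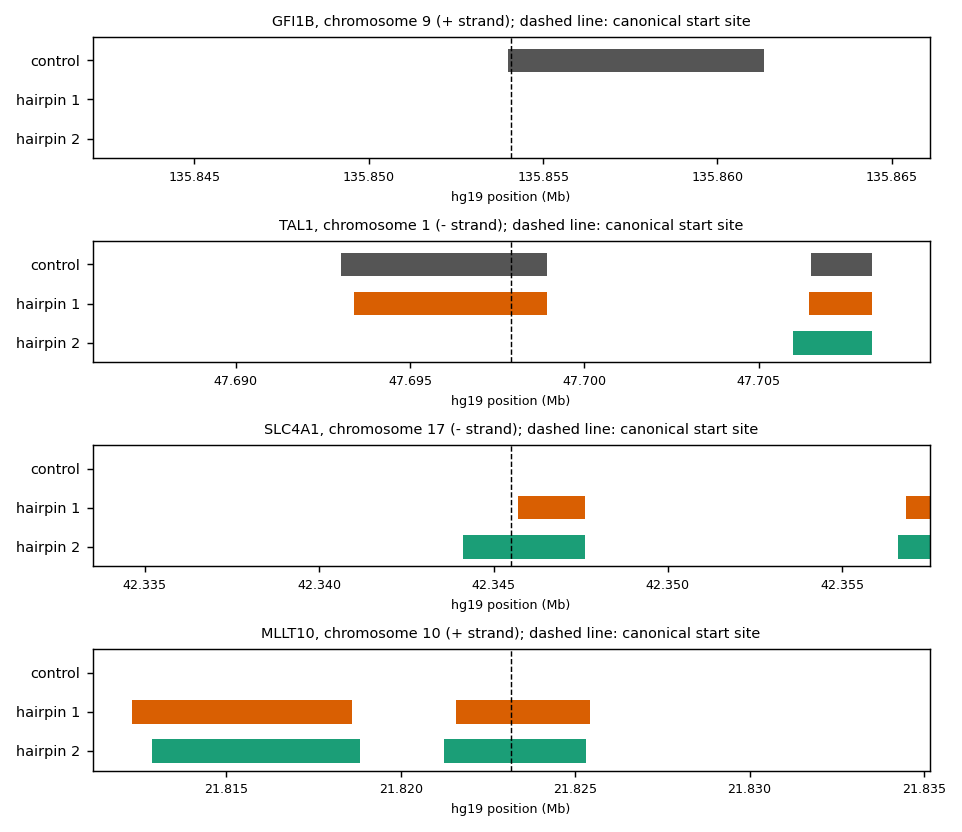
H3K27ac peaks of each library as bars along hg19 (x axis, Mb) at GFI1B, TAL1, SLC4A1 and MLLT10, with dashed lines at the canonical start sites. The GFI1B peak appears in the control alone, the TAL1 promoter peak in the control and hairpin 1, and the SLC4A1 and MLLT10 promoter peaks in both hairpins and not the control.

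Markers of other lineages differed in both directions. Megakaryocyte markers, which K562 cells partly express, had means of 1968 bp in the control, 1452 bp in hairpin 1 and 1129 bp in hairpin 2 (percentile 0.05). ITGA2B, platelet integrin alpha-IIb, had 8040, 2035 and 3613 bp, and GP1BB, a subunit of the platelet receptor for von Willebrand factor, had 6712, 6409 and 0 bp. These 2 genes made up most of the difference in the mean, and the median difference of the list was 0 bp. Of the 13 genes, 3 were retained and 8 had no promoter peak in any list. Myeloid markers had means of 688, 1651 and 914 bp (percentile 98.7), with AZU1, a neutrophil granule protein, at 2321, 4953 and 3336 bp and SPI1, the myeloid regulator PU.1, at 2693, 3788 and 3002 bp. Their position came from hairpin 1 (percentile 99.9) more than from hairpin 2 (60.0). Lymphoid markers had means of 263, 666 and 514 bp (percentile 98.3), and 10 of the 12 had no promoter peak in any list. Their median difference was 0 bp. CD3D had 0, 2025 and 3551 bp and CD2 had 1973, 1695 and 1718 bp. CD79A, chosen after its values were seen, had 0, 2718 and 0 bp. Liver markers had means of 0, 77.6 and 217 bp (percentile 92.5), from 2 genes: TF with 0, 0 and 2167 bp and APOA1 with 0, 776 and 0 bp. Neuron markers had means of 252, 355 and 435 bp (percentile 87.2), with GAD1 at 1476, 2566 and 3229 bp and SLC17A7 at 1049, 983 and 1125 bp.

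Promoter peaks were counted in stress and housekeeping groups as well. All 16 genes of the integrated stress response had a promoter peak in every list, with means of 3673, 3128 and 3464 bp (percentile 2.10). The list came inside in each hairpin alone (2.89 in hairpin 1 and 6.94 in hairpin 2) and in narrower width bins, a matching chosen after seeing the data (2.89, or 5.50 with those bins alone). ATF4, its central transcription factor, had 4146, 5448 and 6327 bp, and DDIT4, an inhibitor of mTORC1 signalling, had 6066, 4504 and 6097 bp. Among members chosen after their values were seen, SLC7A11, the cystine importer, had 6893, 4196 and 3779 bp and DDIT3, which encodes CHOP, had 7052, 4108 and 4705 bp. Of 18 interferon response genes 9 were retained, 5 had no promoter peak in any list and 0 were lost in both hairpins. The means of the list were 1468, 1168 and 1152 bp (percentile 1.68). Of the 18 genes IRF1 was at 4778, 5266 and 0 bp and STAT2 at 3097, 2842 and 2950 bp. This list came inside in hairpin 1 alone (3.45) and when matched on sequence within 25 kb, chosen after seeing the data (4.84 in 10 bins and 3.23 in 20). IFIH1, the RNA sensor MDA5, was chosen after its values were seen and had 3013, 471 and 426 bp. Apoptosis genes retained 11 of 13, with means of 3312, 3201 and 3409 bp (percentile 21.4), among them BBC3, which encodes PUMA (6359, 6050 and 6178 bp), and CASP9 (6351, 2551 and 6919 bp). Cytosolic ribosomal protein genes retained 17 of 20, with means of 4110, 4031 and 3918 bp (percentile 6.04, or 0.41 in the higher-scoring 50%), including RPL8 (4611, 8107 and 4971 bp) and RPS6 (5419, 5956 and 4477 bp).

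In all, 6 of the 20 lists lay outside the central 95% of matched random lists, where about 1 would lie by chance if genes varied independently. Of 100 random lists of 15 genes, 7 lay outside. The random lists took no account of neighbouring genes that share a peak, so more than 1 fixed list may lie outside by chance. With the higher-scoring 50% of each peak list all 6 came inside, at percentile 74.0 for erythroid transcription factors, 89.6 for megakaryocyte, 38.8 for myeloid, 83.2 for lymphoid, 64.4 for stress response and 3.40 for interferon genes. In each hairpin alone 3 lists lay outside, with megakaryocyte markers the one list outside in both (1.29 in hairpin 1 and 0.13 in hairpin 2). Over gene bodies 3 of the 6 came inside, megakaryocyte markers at 12.3, erythroid transcription factors at 9.90 and stress response genes at 4.30. With nearby peaks under 5 kb these were at 21.7, 7.25 and 15.9, and myeloid markers at 97.2. Myeloid and lymphoid markers came inside when also matched on the widest nearby peak, a matching chosen after seeing the data (89.3 and 81.6), and with equal list lengths myeloid markers (96.7) and interferon genes (2.52) did. Mean and median differences had opposite signs in 4 lists, where the median was above 0: red cell membrane (126 bp), oxidative phosphorylation (7.50 bp), apoptosis (172.5 bp) and ribosomal proteins (36.5 bp).

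**Figure D4:**
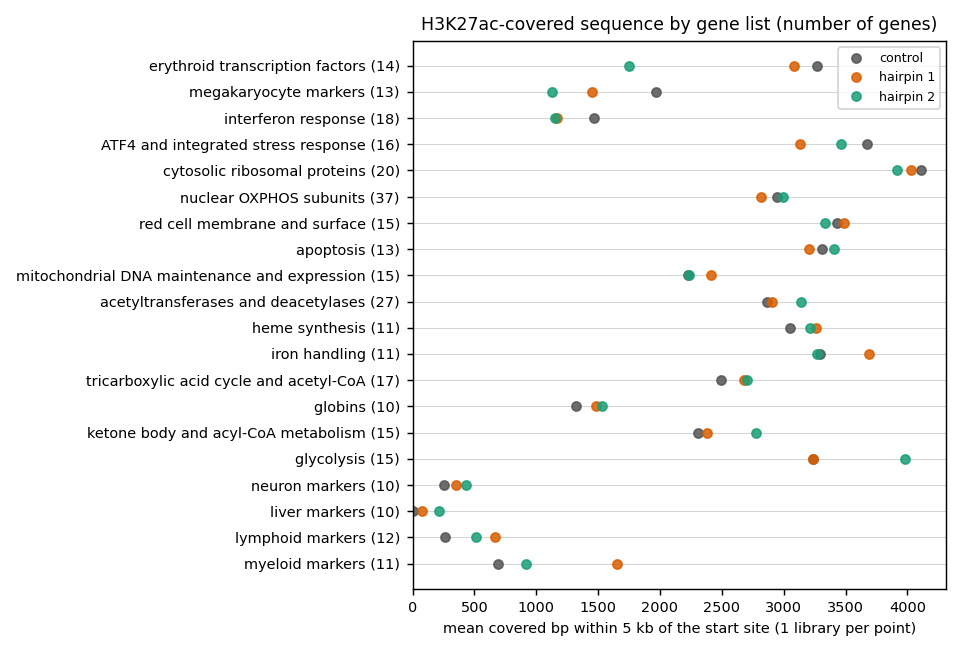
Mean H3K27ac-covered base pairs within 5 kb of the start site (x axis) for each of 20 gene lists (y axis, number of genes in brackets), with 1 point per library. Erythroid transcription factors sit at 3266 bp in the control, 3085 bp in hairpin 1 and 1748 bp in hairpin 2, and myeloid markers at 688, 1651 and 914 bp.

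The widest marked domains were the least reproducible among peaks of 3 kb and more. Promoters of highly active genes, such as that of the translation elongation factor EEF1A1, can carry H3K27ac over several kb. Control peaks of 3 to 4 kb lacked a counterpart in hairpin 1 in 6.09% (5.25 to 7.02) and in hairpin 2 in 4.65% (3.92 to 5.48). Control peaks of 7 to 9 kb lacked one in 20.5% (15.02 to 26.97) and 25.3% (19.3 to 32.1). The same held between the hairpins, where 21.6% of hairpin 1 peaks of 7 to 9 kb were missing from hairpin 2 and 14.7% of hairpin 2 peaks of that width were missing from hairpin 1. Wide peaks ranked low within their own lists, with a median score percentile of 26.6 in the control at 7 to 9 kb and 76.5 at 3 to 4 kb. Control peaks of any width at score percentile 20 to 30 lacked a counterpart in 40.2% (38.2 to 42.2) in hairpin 1 and in 31.2% (29.3 to 33.1) in hairpin 2, above the interval of the widest peaks in hairpin 1 and within it in hairpin 2. The lost GFI1B peak was of this kind, at 7351 bp and score percentile 2.51 (chromosome 9, 135853985 to 135861335).

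**Figure D5:**
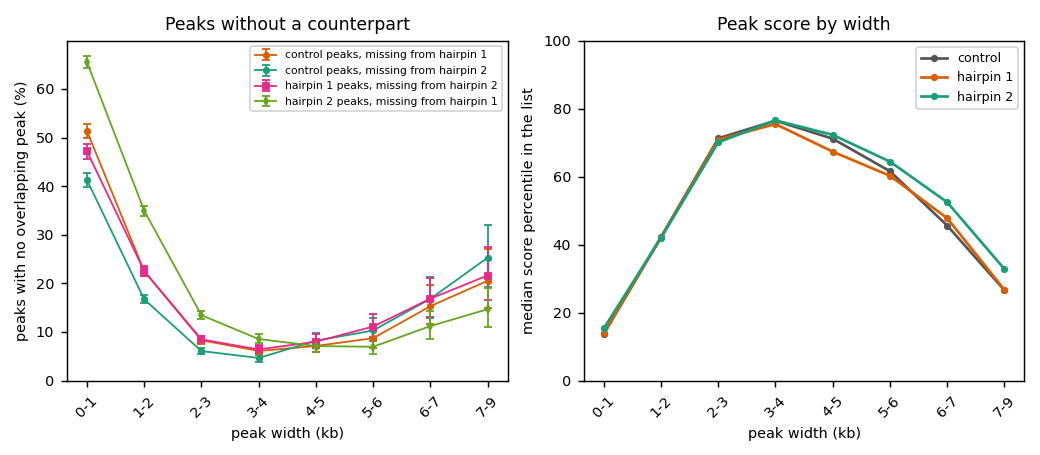
Left, percentage of peaks of each width (x axis, kb) with no overlapping peak in another library, with exact 95% intervals; right, median score percentile of peaks within their own list by width. The missing share of control peaks in hairpin 2 is 4.65% at 3 to 4 kb and 25.3% at 7 to 9 kb, and the median control score percentile goes from 76.5 to 26.6.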

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

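Chosen after the results were seen were the tests of promoters, of shared new regions and of a shared TFAM effect, the test of peaks near the calling threshold, both tests of wide promoters and the matchings of random lists on G+C and on the widest nearby peak; the test of shared widths by G+C was written first.

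For 4 gene lists the hairpins moved in opposite directions from the control in mean covered base pairs, and none of these differences was tested. Iron handling genes were at 396.6 bp above the control in hairpin 1 and at -24.9 bp in hairpin 2. Red cell membrane and surface genes were at 56.9 bp and -93.1 bp. Nuclear genes of oxidative phosphorylation were at -126.2 bp and 47.4 bp. Apoptosis genes were at -110.9 bp and 96.6 bp.

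Regions found in the control alone were poor in G+C (median 40.9%) and regions gained in both hairpins were richer (50.4%). A change confined to promoters is argued against, because outside promoters the ratio of gained to lost regions was 18.6 times as high in the highest of 5 G+C groups as in the lowest. TFAM depletion giving both hairpins the same new regions stays open: the gained count was 0.832 times that of libraries that do not stand apart, but it was inside its range in the higher-scoring 50% of each list (1049 against 1072), and the model ties its shortfall to that of lost regions. A G+C-dependent difference in recovery between the libraries made a prediction for shared regions. Their median log2 width ratio would be higher in the highest than in the lowest G+C group by more than 0.05 in both hairpins. The smaller of the 2 differences was 0.36. For hairpin 2 over hairpin 1 the difference between the same groups was -0.15. Unequal recovery by G+C may account for the pattern. With 1 library per group an effect of TFAM depletion on G+C-rich chromatin was not excluded.

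Erythroid transcription factor promoters carried less marked sequence in the hairpin lists, at percentile 0.04 of random lists, mainly through TAL1, ZFPM1 and IKZF1 in hairpin 2 and GFI1B in both. The list stayed at 0.77 when also matched on the widest nearby peak and at 0.02 when also matched on promoter G+C. Peak width and promoter G+C, as matched, therefore did not account for its position. Loss of wide domains and a difference in G+C recovery are not excluded by this. Both matchings were chosen after the results were seen and took no account of peak score. Control peaks at score percentile 0 to 10 lacked a hairpin 2 counterpart in 49.5%, and those at 90 to 100 in 0.56%. Among genes with nearby peaks under 5 kb the list came inside at 7.25. That setting leaves out TAL1, ZFPM1, IKZF1 and GFI1B and so decides neither way. Peaks near the calling threshold stay open: with the higher-scoring 50% of each list the percentile was 74.0, where IKZF1 and GFI1B fell to 0 bp in every list, but LMO2 (0, 4865 and 4705 bp) and GATA2 (0, 2903 and 0 bp), named after their values were seen, then left the control, TAL1 and ZFPM1 were still missing from hairpin 2, and the 4 control promoter peaks absent from hairpin 2 had a median score percentile of 48.4. An effect of TFAM depletion shared by both hairpins cannot be told apart from one of the hairpin 2 library, because hairpin 1 alone stood at 16.9. A change particular to the hairpin 2 cells or library may therefore be the larger part of the pattern.

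The promoters with the largest shared changes went from no peak to one of several kb or back, as at EEF1A1 (0, 6972 and 7516 bp) and at CLIC1, a chloride channel family gene (7973, 0 and 0 bp), named after their values were seen. No list held a peak wider than 8841 bp, and whether wider domains were left out is not known. A value of 0 bp therefore does not show that a promoter was unmarked. Peaks dropping out of wide domains whatever the condition is a candidate explanation, since between the hairpins peaks of 7 to 9 kb lacked a counterpart 3.37 times as often as peaks of 3 to 4 kb in one direction, but 1.72 times in the other, short of the factor of 2 asked for. Shared TFAM depletion predicted at least 2 times as many promoters with a nearby peak of 6 kb or more gained in both hairpins as absent from either single hairpin. The ratio to the larger of these counts was 0.688, from 53 gained, 77 absent only from hairpin 2 and 35 absent only from hairpin 1. Another 33 such promoters had a peak in the control alone. Neither explanation can be told apart from the other, because the gained count lay between the 2 single-hairpin counts. The low scores of wide peaks (median percentile 26.6 in the control) may come from a background estimated over neighbouring marked sequence, a step not given in the sources used here.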

How the results depend on the processing

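Added after seeing the data were the settings with peaks under 5 kb, all basic start sites and the extra matchings of random lists. Of the values that answer a comparison, 51 were classed as the same as the reported one and 34 as moved. Some of the 51 were not close. With equal list lengths, 1510 gained and 2887 lost regions were counted, against 2001 and 2386 with all peaks. Of the percentiles of the 6 outlying lists, 38 stayed outside on the same side and 30 came inside on the same side of the middle. The other 4 came inside on the other side of it. With the higher-scoring 50% of each list, peaks numbered 11706, 11909 and 13503 by construction, overlap of control peaks was 84.4% in hairpin 1 and 88.5% in hairpin 2, and that of hairpin 1 peaks in hairpin 2 was 87.8%. Gained regions then numbered 1049, lost regions 855 and gained genes 567, and the promoter share was 76.5% in all lists, 48.5% in gained and 15.4% in lost regions. Percentiles came inside across the middle at 74.0 for erythroid transcription factors, 89.6 for megakaryocyte, 38.8 for myeloid and 64.4 for stress response genes, while 4 lists inside before lay below 2.5: heme synthesis at 1.35, red cell membrane at 0.69, oxidative phosphorylation at 0.39 and ribosomal proteins at 0.41. With equal list lengths the overlap in hairpin 2 was 79.3% of control and 76.7% of hairpin 1 peaks, and the promoter share in all lists 53.9%. With 50% overlap, 82.9% of control peaks were in hairpin 2. With promoters of 2.5 kb on each side the share of lost regions was 8.38%. Hairpin 1 alone, which asks for less by construction, gave 5287 gained and 4827 lost regions, 55.2% wider, 641 gained and 436 lost genes and 3 outlying lists. Hairpin 2 alone gave 7398 and 3838 regions, 63.7% wider, 647 and 411 genes and 3 lists. In regions under 5 kb the promoter share was 11.5% of gained and 5.43% of lost regions. Matching on narrower width bins as well, or on sequence within 25 kb in 10 or 20 bins, left 3 outlying lists each. Apart from the effects of construction, the cause was not tested. Depth was unknown and limits what an absent peak can show. No paired analysis was possible because each group had 1 library.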

Other observations

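The tests of chromosome M, of chromosome 22 and of the length of the hairpin 2 list were chosen after the results were seen; the test of symbol families was written first.

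Outside the fixed lists, the genes with the largest shared changes in covered sequence within 5 kb of the start site, included those below, chosen after their values were seen. KMT2E, a chromatin protein of the MLL family, had 0 bp in the control, 7437 bp in hairpin 1 and 8491 bp in hairpin 2. PTGES3, the HSP90 co-chaperone p23, had 0, 7891 and 7326 bp, and YES1, a SRC-family kinase, had 0, 6849 and 7825 bp. The deubiquitinase gene USP15 had 0, 6837 and 7424 bp. In the other direction, BCOR, a repressor of a Polycomb complex, had 7267, 0 and 0 bp. SREBF1, the regulator of lipid synthesis genes, had 6816, 0 and 0 bp, CCND3, the D-type cyclin of erythroid precursors, had 6624, 0 and 0 bp, and RNF213, a ubiquitin ligase, had 7295, 0 and 0 bp. Among 12780 genes covered in at least 1 list, 5292 had more covered sequence in both hairpins, 2798 had less in both and 3918 moved in opposite directions. Taken singly, 7080 had more and 5294 less in hairpin 1, and 8185 had more and 4229 less in hairpin 2. Part of the agreement between the hairpins can come from the control library that both share.

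Of the 62 symbol families 4 lay outside the central 95% in hairpin 1 alone and 4 in hairpin 2 alone, and the 2 given next were chosen from them after their values were seen; the difference between the hairpins was not tested. The 61 covered genes with symbols starting with H and a digit, nearly all of them histone genes, were at percentile 99.8 of random lists in hairpin 1 and at 0.30 in hairpin 2. The random lists were not matched on position, so neighbouring genes that share a peak can make such percentiles more extreme. The 425 covered ZNF genes, which encode zinc finger proteins, were at 0.05 in hairpin 1 and at 93.3 in hairpin 2. In both hairpins together, leucine-rich repeat genes (LRRC, percentile 99.0) and coiled-coil domain genes (CCDC, percentile 98.7) lay outside the central 95%. Of the 62 families, 3.23% lay outside, no more than chance gives. Within the red cell lists, promoters missing from 1 hairpin alone, chosen after their values were seen, included ALAS2, the first enzyme of erythroid heme synthesis (2506, 0 and 5738 bp), and GYPC, glycophorin C (6366, 7034 and 0 bp). ANK1, the ankyrin of the red cell skeleton, had 0, 6669 and 0 bp, and RHAG, of the Rh complex, had 7836, 5927 and 0 bp.

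A peak on mitochondrial DNA (chromosome M, 20 to 4599) was listed in the control alone, with score percentile 14.7, and 29.4% (27.1 to 31.8) of 1469 control peaks of similar score had no counterpart in either hairpin. That share does not tell whether the libraries differed in their content of mitochondrial DNA, which was not measured here. On chromosome 22 from 19 to 22 Mb, where SLC25A1, PI4KA and RIMBP3C lie, 9.17% (4.67 to 15.8) of 120 regions were listed in the control alone, against 7.04% of all other regions, and 10.0% (5.27 to 16.8) were gained, against 5.90%. Peaks found in hairpin 2 alone had a median score percentile of 18.0 within its list, against 15.6 for the control alone and 16.0 for hairpin 1 alone. Single-list peaks thus ranked low in every library, and this value does not tell why the hairpin 2 list was the longest. Hairpin 1 had 1.02 times as many peaks as the control.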
